A study of Mus musculus with 20 samples.

How the data were processed

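RNA from mouse lung was sequenced in 20 libraries, 5 from each of 4 groups named in the labels: control, model, SMD and prednisone. The series title places the work in asthma and names SMD as Shegan-Mahuang Decoction, a traditional Chinese herbal formula. Per the design text, each group held 15 mice and lung tissue of all 4 groups was sequenced. How the model was made, the doses and the times of collection are not given in the sources used here. Group and replicate number were taken from the labels of each library. The treatment label of prednisone replicate 5 carries another replicate number than its title, and the title was used. The labels name the libraries of a group as separate samples but not explicitly as separate animals, so the p-values measure only the spread between these samples, which may in part be technical.

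Per the labels' protocols, RNA was extracted with TRIzol and libraries were prepared with a NEBNext Ultra RNA kit and sequenced as paired reads on an Illumina NovaSeq instrument. The authors deposited FPKM values (fragments counted per gene, scaled to the length of the gene and the number of mapped fragments) for every gene and library. Per the submitters' processing notes, fastp, HISAT2, featureCounts and DESeq2 and the mouse genome build GRCm38 were used by the authors. The notes give no versions or order of steps, and which of these programs made the FPKM values, from which annotation and with which strand setting is not given in the sources used here. The table held 54532 Ensembl gene identifiers, of which 54409 could be paired with a gene symbol and 54495 were found in the GENCODE annotation vM21 of GRCm38. Positions, biotypes, gene lengths and GC contents come from that annotation. No value above 0 was listed for 16574 genes.

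FPKM values hold no counts. To learn whether depth could be recovered, the low values of 13223 single-exon genes were tested for whole multiples of the value of 1 read. At best, 13.3% to 16.8% of values per library lay within 0.05 of a whole number, where 10% is given by chance, so the depth of each library is unknown and no counting interval or floor is given. The sum of the FPKM values per library ranged from 377639 to 522361.

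Values were analysed as log2(FPKM + 1) without further scaling. Genes with an FPKM of 1 or more in at least 5 of the 20 libraries were tested, which left 15106. The pseudocount of 1 makes a fold change understate the change of genes with low values. Group means were fitted with limma 3.58.1 in R 4.3.3 (lmFit, then eBayes with an intensity trend), in 1 fit over all 20 libraries without covariates, since the labels name no batch. The fit has 16 residual degrees of freedom and 19.1 after moderation. Tests were two-sided, p-values were adjusted by the Benjamini-Hochberg method over all genes tested within a comparison, and a gene was called at an adjusted p under 0.05. The comparisons were model with control, SMD with model, prednisone with model, SMD with prednisone, and each treatment with control. Values are given as mean ± SD in FPKM over 5 libraries, and log2 fold changes with their standard error (SE).

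The design, the alternatives, the rule for naming genes and 41 gene lists of immune, epithelial, vascular, metabolic, stress, clock and hormone-response genes and of tissues that a dissected lung can carry with it were fixed before the data were examined. By that rule, the 12 largest rises and the 12 largest falls were named for each comparison with the model or of the model with control, and the 6 largest each way for the other comparisons. They were taken among called genes whose groups of 5 libraries did not overlap, leaving out predicted genes, immunoglobulin and T cell receptor segments and pseudogenes. For each list described, up to 4 called members with the largest change were named, and 20 genes of asthma and of the glucocorticoid response were given whatever their result. Some genes that the rule or a count would name are not reported here. Junb, Gm26619 and Hist2h2aa1, the genes overlapping named small RNAs, and the clock genes tested on their own other than Arntl and Npas2 were chosen after their values were seen. Lists were tested with camera in limma with a preset correlation between genes of 0.01, adjusted over the 41 lists of a comparison, and again with the correlation estimated for each list. Calls of list members were also adjusted over the list alone.

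Comparisons that share libraries share chance values. Overlaps and correlations between them were therefore set beside 100 simulations of unchanged groups (counts of calls, and lists as long as the real ones taken by the smallest p, the latter added after the data were seen), beside the overlap of independent lists, and beside 20 splits of the model libraries into separate sets. Each count of calls was also set beside 100 other splits of the same libraries into groups of 5. A few clock genes were tested with exact permutation tests over all 252 arrangements of 10 libraries.

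The procedure was tested on simulated data made from the mean and SD of each gene in these libraries, with 50 genes changed by each size. The changed genes were drawn from those with higher means, and noise was drawn independently for each gene and library. Correlation between genes and shifts of whole libraries were thus absent, so the shares below test the procedure and do not give the recovery or false calls in the real data. For model against control, 76% of genes changed by 0.5 on the log2 scale, 100% of those changed by 1 and 92% of those changed by -1 were recovered, and 7.07% of calls were false. For SMD against model, these shares were 80%, 96% and 96%, with 4.12% false calls. For prednisone against model, they were 80%, 98% and 96%, with 4.1% false calls.

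Alternatives were median-of-ratios scaling, quantile normalization, a pseudocount of 0.1, no filter, a filter at an FPKM of 5, eBayes without trend, library weights (arrayWeights), a fit over only the groups compared, the replicate number as a block, a minimum absolute log2 fold change of 1, and leaving out each library. A fat score (the mean log2 value of the fat tissue list per library) as a covariate and a correction for gene length and GC content were added after the data were seen. The reference tables were read and the figures drawn with Python 3.11.15, pandas 2.3.3, numpy 2.4.6 and matplotlib 3.10.9.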

Results

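Gene expression was measured by RNA sequencing in mouse lung in 4 groups of 5 libraries: a control group, an asthma model, and the model given either SMD (Shegan-Mahuang Decoction, a herbal formula) or prednisone, a synthetic glucocorticoid. An FPKM of 1 or more was listed for 14102 to 14707 genes per library. The FPKM values of a library summed to between 377639 and 446711 in 19 libraries and to 522361 in control replicate 1. In that library, the abundant non-coding 7SL and 7SK RNAs took 7.21% of the sum, against at most 0.84% in any other. Across genes, the correlation of log2 values between pairs of libraries lay between 0.946 and 0.982. The depth of the libraries is unknown, so precision was judged from the spread between libraries alone. The median standard error of a log2 fold change between groups was 0.105.

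The model was compared with the control group to find how the lung differed in the asthma model. The genes that rose in the model lungs included the immunoglobulin genes Ighg2b and Igha and the MHC class II genes H2-Ab1, H2-Eb1 and Cd74. Ighg2b, the constant region of IgG2b (chromosome 12, 113302965 to 113307933, GRCm38), rose from 0.299 ± 0.223 FPKM in the control group to 5.53 ± 5.08 FPKM in the model group (SD, n = 5 each), with a log2 fold change of 2.07 ± 0.385 (SE; adjusted p = 0.0422). Igha, the constant region of IgA, rose from 6.19 ± 1.61 to 31.9 ± 21.8 FPKM, and Ccl17, a chemokine that attracts T helper type 2 cells, rose from 3.4 ± 1.19 to 8.96 ± 3.52 FPKM. H2-Ab1 and H2-Eb1, chains of the MHC class II molecule, rose by 0.77 and 0.81 on the log2 scale, and Cd74, the invariant chain that guides class II molecules, rose from 372 ± 37.7 to 639 ± 128 FPKM. The plot of immunoglobulin and MHC class II genes gives the value of each library.

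**Figure D1:**
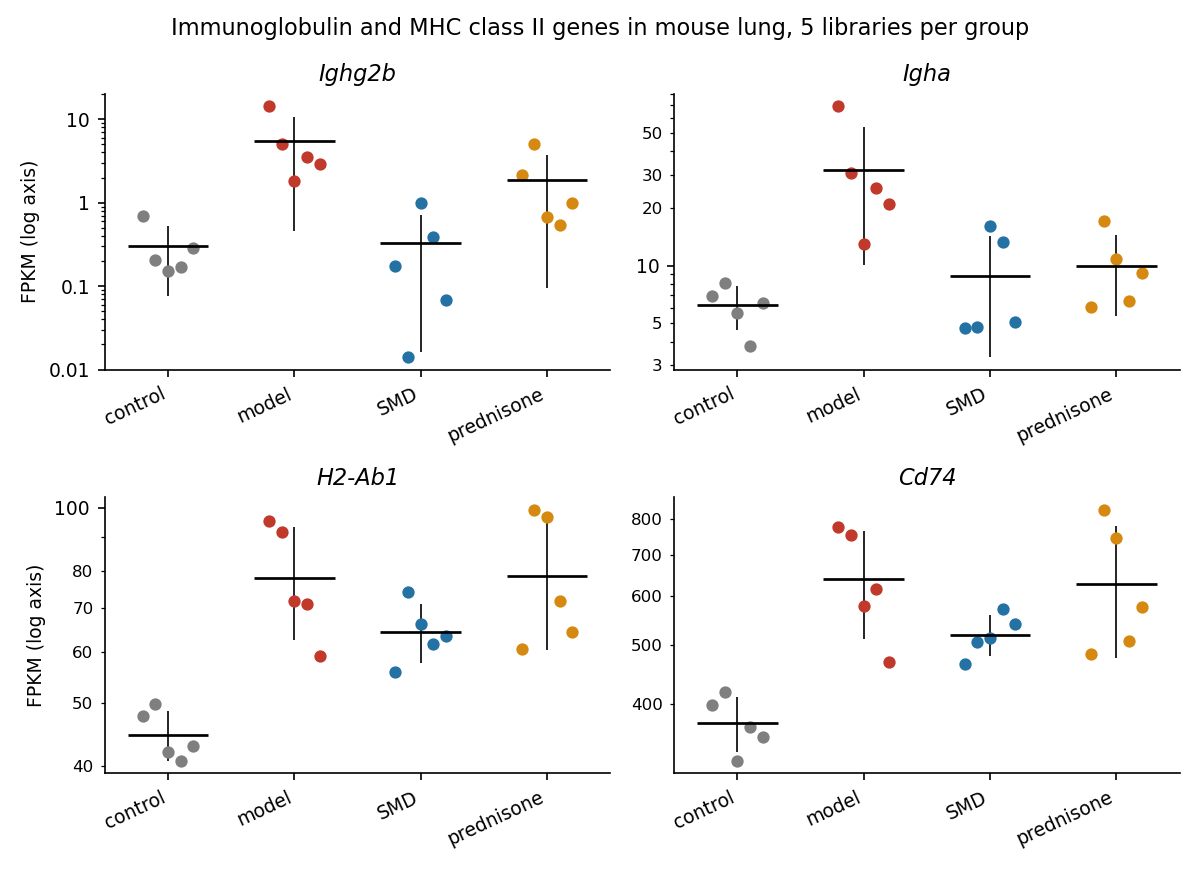
FPKM (log axis) of Ighg2b, Igha, H2-Ab1 and Cd74 in each of the 5 libraries per group (points), with the group mean (horizontal line) and SD (vertical line, shortened where it would reach 0). All model libraries lie above all control libraries for the 4 genes, and Ighg2b fell from 5.53 ± 5.08 FPKM in the model to 0.326 ± 0.395 FPKM in the SMD group.

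Limma called 29 genes between model and control, of which 29 rose and 0 fell. At an unadjusted p under 0.05 there were 2381 genes (1957 higher and 424 lower), where 755 are expected by chance. The excess of rises depended on scaling: 951 were higher and 968 lower with median-of-ratios scaling, and 1006 and 903 with quantile normalization. The other genes named by the ranking were C1qa (a chain of complement C1q, log2 fold change 0.64), Alkal1 (a ligand of the receptor ALK, 0.67), Vmp1 (a membrane protein of autophagy, 0.50), Fut4 (a fucosyltransferase, 0.52) and the microRNA genes Mir5107 (0.74) and Mir7115 (0.54). Mir5107 lies inside Cd74 and Mir7115 inside Arrb2, and reads of the host genes cannot be told apart from theirs, so both values are uncertain. Values of the 5 model and the 5 control libraries did not overlap for 479 genes (3.17%, where chance gives 0.79%). This count and those of the other comparisons below were made without further scaling, so a shift of whole libraries can add to them. Here the median log2 fold change of all genes was 0.055.

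Among the 19 measured genes of plasma cells and immunoglobulin constant regions, 2 rose (Ighg2b and Igha) and 17 did not pass, while 10 rose when adjusted over the list alone. The list median was 0.41 (camera, adjusted p = 0.000173; adjusted p = 0.365 with an estimated correlation). Of 69 immunoglobulin variable segments, 1 rose, and 63 of the 69 had positive log2 fold changes, with a median of 0.61. In the list of dendritic cells and MHC class II, 3 of 12 genes rose (H2-Eb1, H2-Ab1 and Cd74; 7 adjusted over the list alone), with a median of 0.55 (adjusted p = 0.000537; adjusted p = 0.365 with an estimated correlation). In the list of complement and phagocytic macrophages, 1 of 17 rose (C1qa; 9 adjusted over the list alone), with a median of 0.54 (adjusted p = 9.09e-05; adjusted p = 0.498 with an estimated correlation). In limma, 0 members of the lists of endothelial cells, mitochondrially encoded genes and B cells passed, and 6, 7 and 0 were lower at an unadjusted p under 0.05. Their medians were -0.19, -0.21 and -0.16 (camera adjusted p = 6.43e-07, 2e-09 and 0.0156; adjusted p = 0.365, 0.365 and 0.618 with an estimated correlation). In all, camera called 18 of 41 lists, 9 higher and 9 lower, and 0 with an estimated correlation. Markers of fat tissue and of cardiac muscle had medians of -0.58 and -0.42 in the same comparison. None of the 9 measured genes of either list passed in limma, and 1 of each was lower at an unadjusted p under 0.05.

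Several genes of allergic inflammation stayed under the filter, which counts libraries over all groups together. In the model, Il4 was at 0.507 ± 0.165 FPKM, Il13 at 0.0592 ± 0.0445 FPKM, Il5 at 0.0936 ± 0.0589 FPKM, Muc5ac (the secreted airway mucin) at 0.103 ± 0.0502 FPKM and Epx (eosinophil peroxidase) at 0.00916 ± 0.0126 FPKM. In control, SMD and prednisone libraries, Il4 was at 0.321 ± 0.0901, 0.413 ± 0.141 and 0.359 ± 0.052 FPKM. In the same order, Il13 was at 0.00608 ± 0.0106, 0.0212 ± 0.0292 and 0.00375 ± 0.00838 FPKM, and Il5 at 0.075 ± 0.0676, 0.203 ± 0.0679 and 0.107 ± 0.061 FPKM. Muc5ac was at 0.111 ± 0.05, 0.114 ± 0.0293 and 0.091 ± 0.0245 FPKM, and Epx at 0.0148 ± 0.0157, 0.0131 ± 0.0149 and 0.0082 ± 0.0146 FPKM. Clca1, Arg1, Il6, Tnf and Ccl24 likewise did not pass the filter and were not tested. In the model, Clca1 was at 0.0641 ± 0.0286 FPKM, Arg1 at 0.749 ± 0.159 FPKM, Il6 at 0.248 ± 0.289 FPKM and Ccl24 at 0.776 ± 0.375 FPKM. Tnf was at 1.23 ± 0.679 FPKM in the model and 0.572 ± 0.218 FPKM in control. It was at 0.41 ± 0.09 FPKM under SMD and 0.458 ± 0.382 FPKM under prednisone. Il33, an epithelial alarmin, was at 15.6 ± 2.26 FPKM in control and 22.5 ± 1.23 FPKM in model lungs (adjusted p = 0.0826), and Il1b at 3.03 ± 0.882 and 7.25 ± 3.45 FPKM (adjusted p = 0.167). Log2 fold changes of Ccl11, Retnla, Chil3 and Scgb1a1 were -0.14, 0.29, 0.24 and -0.16, and none of them passed. Under median-of-ratios scaling or quantile normalization, limma called 0 genes between model and control, with 1919 and 1909 genes at an unadjusted p under 0.05. Without control replicate 1, which holds the high 7SL and 7SK share, 1 gene was called, and 0 were called without any other control replicate, model replicate 1 or 2, SMD replicate 1, 2 or 4, or prednisone replicate 3 or 4, against 19 without SMD replicate 5, 51 without model replicate 5 or prednisone replicate 1, and 111 without model replicate 4.

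SMD was compared with the model to find how the decoction changed the lung of the asthma model. The genes that fell in the SMD lungs included Zbtb16 and Fkbp5, both known to be induced by glucocorticoids. Zbtb16, a transcription factor induced by glucocorticoids (chromosome 9, 48654297 to 48836222), fell from 13.8 ± 8.44 FPKM in the model to 1.20 ± 0.359 FPKM in the SMD group (log2 fold change -2.49 ± 0.365, SE; n = 5 each, adjusted p = 0.00343). Fkbp5, a co-chaperone of the glucocorticoid receptor (chromosome 17, 28399094 to 28517527), fell from 19.4 ± 7.43 to 3.49 ± 1.71 FPKM (log2 fold change -2.19 ± 0.371, adjusted p = 0.00651). Ighg2b and Jchain, the chain that joins IgA and IgM into polymers, fell with log2 fold changes of -2.07 and -1.80. Hspa1b, an inducible Hsp70 chaperone, fell from 8.63 ± 4.47 to 2.58 ± 0.823 FPKM, and Mcm2, a subunit of the replicative helicase, rose from 1.78 ± 0.613 to 3.87 ± 0.883 FPKM.

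**Figure D2:**
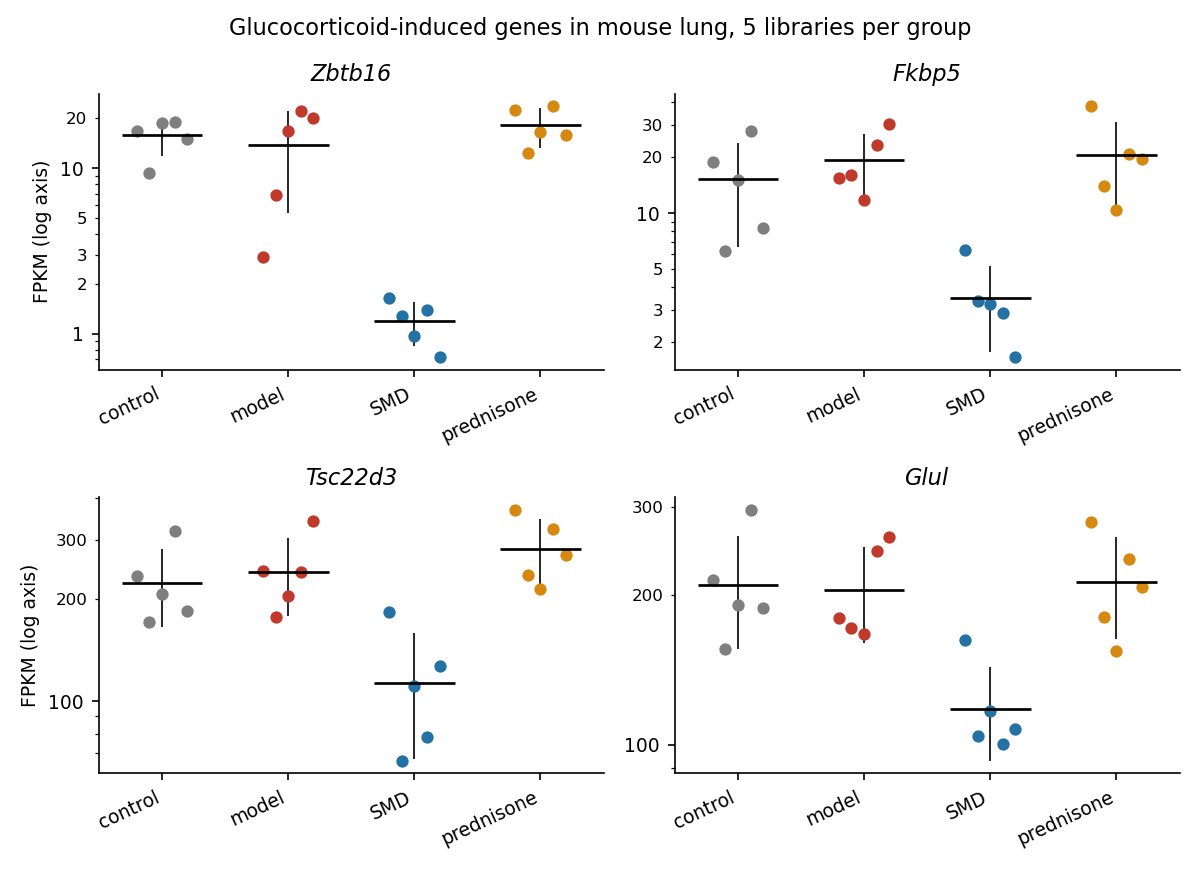
FPKM (log axis) of the glucocorticoid-induced genes Zbtb16, Fkbp5, Tsc22d3 and Glul in each of the 5 libraries per group (points), with the group mean (horizontal line) and SD (vertical line). All 5 SMD libraries lie below all model libraries for Zbtb16, Fkbp5 and Glul, while Tsc22d3 overlaps (up to 183 FPKM under SMD and from 178 FPKM in the model), and Zbtb16 was at 1.20 ± 0.359 FPKM under SMD and 18.1 ± 4.84 FPKM under prednisone.

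Limma called 325 genes, of which 37 rose and 288 fell. Among genes whose SMD and model libraries did not overlap, the largest falls named by the ranking besides Zbtb16, Fkbp5, Ighg2b, Jchain and Hspa1b were those of Klf15 (a metabolic transcription factor, log2 fold change -1.28), Arl4d (-1.04), Bcl2l1 (the survival protein Bcl-xL, -1.04), Tcim (-0.99), Sema7a (a semaphorin, -0.91), Snord47 (-0.90) and Fam13a (-0.86). After Mcm2, the largest rises among such genes were those of Rnf144a (a ubiquitin ligase, 0.74), Tnfsf10 (the death ligand TRAIL, 0.68), Wnt7a (a Wnt ligand, 0.67), Topbp1 (a DNA replication and checkpoint protein, 0.63), Scel (0.57), Cep70 (a centrosomal protein, 0.57), Rnd1 (0.54), Itprid1 (0.54), the long non-coding RNA Ptgs2os2 (0.52) and Lrtm2 (0.52). The microRNA gene Mir5620 rose from 0.324 ± 0.299 to 1.5 ± 0.567 FPKM. Snord47 lies inside Gas5 (log2 fold change 0.06, not called) and Mir5620 lies on the other strand of Clcn4 (0.15, not called), so the source of their reads is uncertain. Of the 24 genes named by the ranking, 21 were still called with median-of-ratios scaling (not Jchain, Arl4d and Bcl2l1), 17 with quantile normalization, 12 with no filter, 10 with only the groups compared, and 2 with the fat score as a covariate (Tcim and Fam13a). The SMD and model libraries did not overlap for 698 genes (4.62%, where chance gives 0.79%).

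Of the 19 measured glucocorticoid-induced genes, 8 fell and 0 rose, and 17 fell when adjusted over the list alone. Tsc22d3, the glucocorticoid-induced leucine zipper, fell with a log2 fold change of -1.14, and Glul, glutamine synthetase, with -0.78. The list median was -0.75 (camera, adjusted p = 9.64e-13; adjusted p = 0.483 with an estimated correlation). Fat tissue markers had a median of -1.0, with 0 of 9 genes passing in limma and 6 lower at an unadjusted p under 0.05 (camera adjusted p = 0.0575), and the fat score was 1.40 ± 0.18 in SMD, 2.44 ± 0.8 in model, 2.94 ± 1 in control and 1.80 ± 0.31 in prednisone libraries. Cardiac muscle markers had a median of -0.46. With the fat score as a covariate, 0 of the 19 glucocorticoid-induced genes passed in limma (16 lower at an unadjusted p under 0.05), and their median was -0.61. The number that fell was 3 with median-of-ratios scaling or the length and GC correction, and 2 with quantile normalization, no filter or only the groups compared. Leaving out 1 library gave 4, 5 and 2 without model replicates 1, 4 and 5, 2, 5, 4 and 4 without SMD replicates 2 to 5, and 13 without control replicate 4.

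In the list of core clock and clock output genes, 6 of 14 fell (8 adjusted over the list alone), among them Ciart (-0.70), a repressor within the clock, and Per2 (-0.50). The list median was -0.29 (adjusted p = 0.000168; adjusted p = 0.483 with an estimated correlation). The number that fell was 2 with median-of-ratios scaling, 1 with quantile normalization and, in limma, 0 with the fat score (7 at an unadjusted p under 0.05). Per1, which is both a clock gene and induced by glucocorticoids, fell with a log2 fold change of -0.43. Among plasma cell and immunoglobulin genes, 3 of 19 fell (Ighg2b, Jchain and Igha; 8 adjusted over the list alone), with a median of -0.63 (adjusted p = 0.000582; adjusted p = 0.797 with an estimated correlation), and 7 of 69 variable segments fell. Of the 19, 1 fell with quantile normalization, the length and GC correction or the fat score. Ccl17 fell with a log2 fold change of -1.06. In the list of immediate early and heat shock genes, 3 of 17 fell (Hspa1b, Hspa1a and Hsph1), with a median of -0.25 (adjusted p = 0.314), while 1 fell with median-of-ratios scaling and, in limma, 0 with quantile normalization, the length and GC correction or the fat score (5 at an unadjusted p under 0.05 in each). Junb, a member of this list, was listed at 0 in control replicates 1 and 5 and SMD replicate 4. Hspa1a and Hspa1b are near-identical copies, and how their reads were divided is unknown.

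Genes of the interferon response had positive log2 fold changes in all 20 measured members under SMD, with a median of 0.23, but limma called 0 of them, over all genes or adjusted over the list alone, and 8 had an unadjusted p under 0.05 (camera adjusted p = 8.17e-10; adjusted p = 0.518 with an estimated correlation). All 16 proliferation genes had positive values, with a median of 0.33, and 1 rose (Mcm2; adjusted p = 1.03e-08; adjusted p = 0.668 with an estimated correlation). In the list of the TCA cycle and respiratory chain, 1 of 24 fell (Cox4i1, a subunit of cytochrome c oxidase, -0.25; 5 adjusted over the list alone), with a median of -0.12 (adjusted p = 0.00108; adjusted p = 0.923 with an estimated correlation). Il33, Retnla and Chil3 had log2 fold changes of -0.35, 0.24 and 0.31 and did not pass. The division into rises and falls depended on scaling: 59 rose and 64 fell with median-of-ratios scaling, and 43 rose and 49 fell with quantile normalization. With the fat score as a covariate 14 genes were called, and leaving out 1 library gave 213 without model replicate 1, 189 without model replicate 2 or 3, 527 without model replicate 4, 76 without model replicate 5, and 75, 131 and 177 without SMD replicates 2, 3 and 5.

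Prednisone was compared with the model to find how a glucocorticoid drug changed the lung of the asthma model. The genes that rose in the prednisone lungs included Iigp1, Gbp7 and Gbp4, and those that fell included Dbp and Iglc2. Iigp1, an immunity-related GTPase (chromosome 18, 60376027 to 60392634), rose from 8.53 ± 2.04 to 23.8 ± 9.70 FPKM (log2 fold change 1.31 ± 0.241, SE; n = 5 each, adjusted p = 0.00621). The guanylate-binding protein Gbp7 rose from 10.4 ± 0.59 to 25.4 ± 9.76 FPKM, and Gbp4 from 13.2 ± 1.27 to 42.4 ± 21.3 FPKM. Dbp, a transcription factor driven by the clock (chromosome 7, 45705088 to 45710203), fell from 82.5 ± 16 to 38.4 ± 11.6 FPKM (log2 fold change -1.11 ± 0.174, adjusted p = 0.00299). The immunoglobulin light chain constant region Iglc2 fell from 34.5 ± 24.1 to 10.3 ± 5.26 FPKM.

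**Figure D3:**
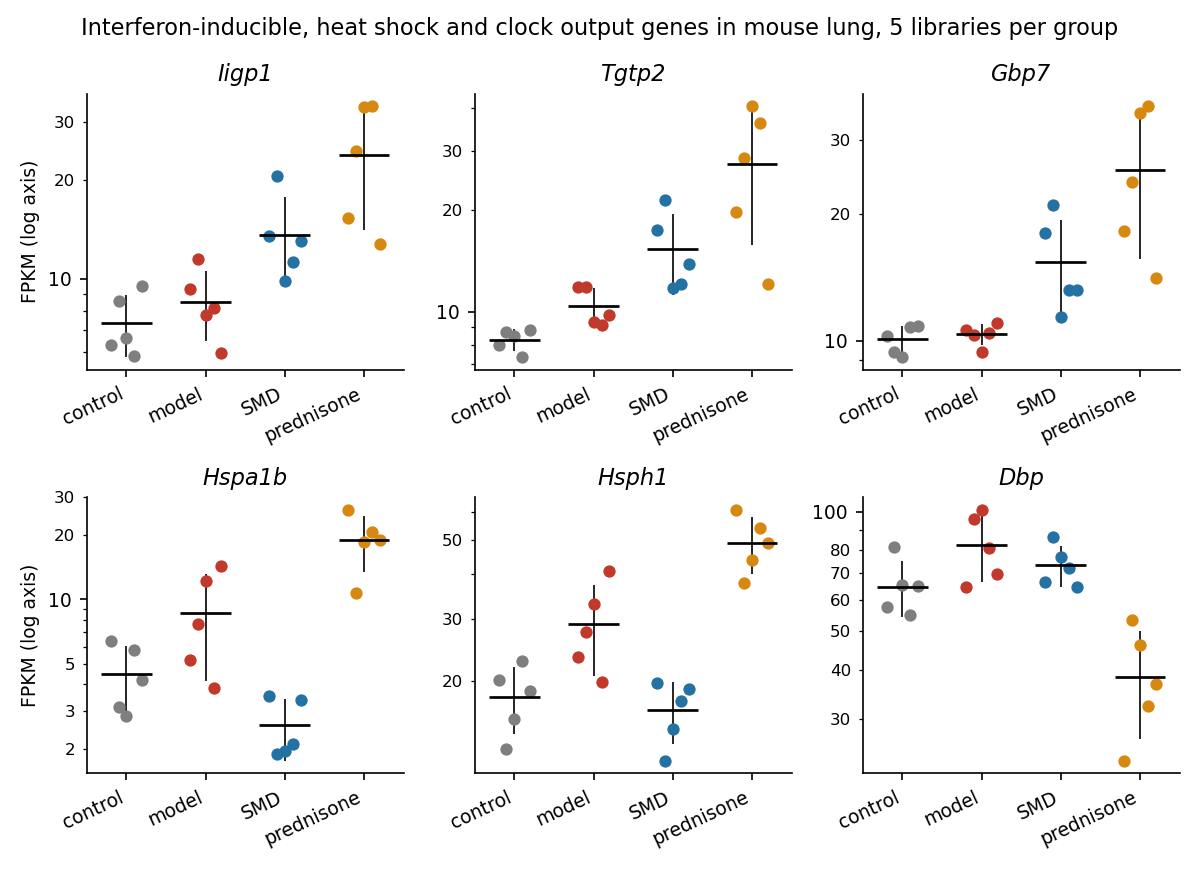
FPKM (log axis) of Iigp1, Tgtp2, Gbp7, Hspa1b, Hsph1 and Dbp in each of the 5 libraries per group (points), with the group mean (horizontal line) and SD (vertical line). All prednisone libraries lie above all model libraries for Iigp1, Tgtp2 and Gbp7, and Dbp was at 38.4 ± 11.6 FPKM under prednisone against 82.5 ± 16 FPKM in the model.

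Limma called 1215 genes, of which 138 rose and 1077 fell. The other rises named by the ranking were Tgtp2 (a T cell-specific GTPase, log2 fold change 1.21), Gbp10 (1.15), Serpina3f (a serine protease inhibitor, 1.14), Gbp6 (1.13), Zfp973 (0.96), Gvin1 (an interferon-induced large GTPase, 0.87), Mir1966 (0.83), Rin2 (0.82) and Smg1 (a kinase of nonsense-mediated decay, 0.75). The other falls were Ccdc42 (-0.85), Nr1d1 (the clock repressor REV-ERB alpha, -0.84), Taf10 (a subunit of TFIID, -0.72), Gja4 (connexin 37 of arterial endothelium, -0.70), Tmem88 (-0.67), Lefty1 (an inhibitor of Nodal signalling, -0.67), Selenom (a selenoprotein, -0.61) and the microRNA genes Mir24-2 (-0.67), Mir7069 (-0.65) and Mir3098 (-0.65). Mir1966 lies inside Ripor1, Mir7069 inside Farsa, Mir3098 inside Mrpl51 and Mir24-2 inside the non-coding Gm26532, and of these hosts Mrpl51 (-0.26) and Gm26532 (-0.38) fell themselves. Tgtp2, Gbp6 and Gbp10 have near-identical copies, and the values of these genes and of the microRNA genes are uncertain. Rin2 and Mir24-2 were not called with median-of-ratios scaling, quantile normalization, no filter, the fat score or the length and GC correction, nor were Ccdc42, Mir7069 and Mir3098 with the last. The prednisone and model libraries did not overlap for 1145 genes (7.58%, where chance gives 0.79%).

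Of 20 interferon response genes, 4 rose (among them Ifi44, Gbp3 and Ifit1, with log2 fold changes of 0.83, 0.63 and 0.62) and 16 did not pass, while 6 rose when adjusted over the list alone. The median was 0.31 (camera, adjusted p = 2.15e-10; adjusted p = 0.637 with an estimated correlation). Of the 20, 2 rose with median-of-ratios scaling, quantile normalization, the length and GC correction or the fat score. Of 17 immediate early and heat shock genes, 3 rose and 2 fell: Hspa1b (1.14), Hspa1a (1.08) and Hsph1 (0.77), all chaperones, rose, and the falls included Ier2 (-0.54), with an adjusted p for the list of 0.0828. Under median-of-ratios scaling, 4 of these 17 rose and 0 fell in limma (2 lower at an unadjusted p under 0.05), and 1 fell with the fat score. Among clock genes, Dbp, Nr1d1 and Ciart (-0.39) fell and Nfil3 (0.48), a repressor of the Dbp targets, rose, and the list as a whole was not called (adjusted p = 0.515). None of the 19 glucocorticoid-induced genes passed in limma, over all genes or adjusted over the list alone, and 1 was higher at an unadjusted p under 0.05. Fkbp5 was at 20.6 ± 10.6 FPKM, Tsc22d3 at 283 ± 63 FPKM and Zbtb16 at 18.1 ± 4.84 FPKM, with log2 fold changes of 0.02, 0.23 and 0.61, and the list median was 0.21 (adjusted p = 0.00147; adjusted p = 0.89 with an estimated correlation).

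Of 20 genes of fatty acid and cholesterol synthesis, 9 fell under prednisone (11 adjusted over the list alone), among them the sterol enzymes Fdps (-0.52), Msmo1 (-0.47), Sqle (-0.42) and Fdft1 (-0.41), with a median of -0.30 (adjusted p = 8.68e-06; adjusted p = 0.559 with an estimated correlation). In the list of the TCA cycle and respiratory chain, 7 of 24 fell (13 adjusted over the list alone), among them Ndufb8 (-0.32) and Cox5a (-0.31), with a median of -0.18 (adjusted p = 8.68e-06; adjusted p = 0.89 with an estimated correlation). With median-of-ratios scaling 5 of 20 and 1 of 24 fell, with quantile normalization 4 and 0 (limma, 10 and 7 at an unadjusted p under 0.05), and with the fat score 7 and 2. Of 23 glutathione and antioxidant enzymes, 5 fell (7 adjusted over the list alone), including Sod3 (-0.44) and Gpx4 (-0.32), with an adjusted p for the list of 0.034 (adjusted p = 0.89 with an estimated correlation), while 3 fell with median-of-ratios scaling or the fat score, 1 with quantile normalization and, in limma, 0 with the length and GC correction (5 at an unadjusted p under 0.05). Of 14 endothelial genes, 3 fell (Sox18, Plvap and Emcn; 3 adjusted over the list alone; 1 with the fat score; in limma, 0 with median-of-ratios scaling and 3 at its unadjusted p under 0.05), with adjusted p = 0.034 for the list (adjusted p = 0.89 with an estimated correlation). Among plasma cell and immunoglobulin genes, 2 of 19 fell (Iglc2 and Igha; 8 adjusted over the list alone), with a median of -0.47 (adjusted p = 0.0119; adjusted p = 0.89 with an estimated correlation). Igha was still called in limma with median-of-ratios scaling and the fat score, but not with the length and GC correction (adjusted p = 0.0679). Of 69 immunoglobulin variable segments, 7 fell, and 64 had negative log2 fold changes. Fat tissue markers had a median of -0.69, with 0 of 9 passing in limma and 0 at an unadjusted p under 0.05. Rises and falls numbered 202 and 299 with median-of-ratios scaling and 153 and 172 with quantile normalization. Leaving out 1 library gave 772, 608 and 636 calls without model replicates 1, 2 and 3, and 789 without prednisone replicate 4.

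**Figure D4:**
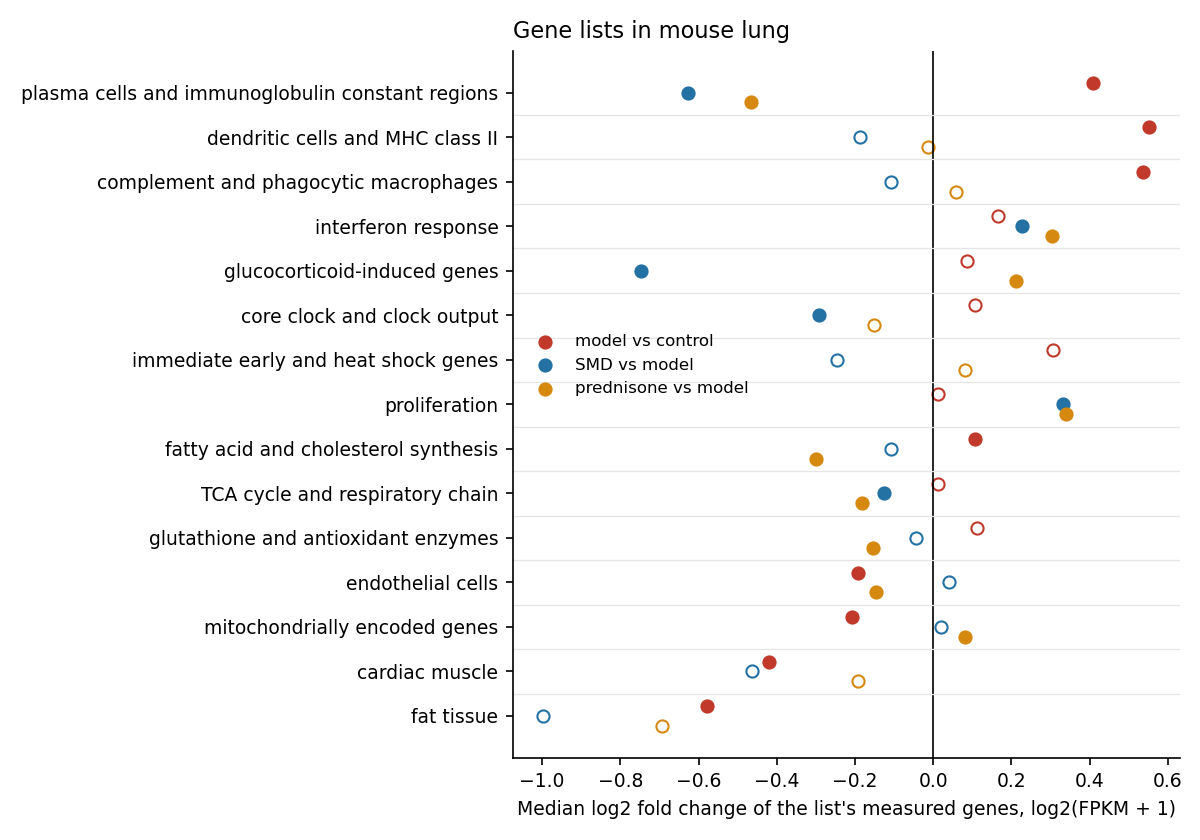
Median log2 fold change, on log2(FPKM + 1), of the measured genes of 15 lists in model against control, SMD against model and prednisone against model. Filled points are lists called by camera with the preset correlation, open points are not called, none is called with an estimated correlation, and the glucocorticoid-induced genes lie at -0.75 under SMD and 0.21 under prednisone.

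**Figure D5:**
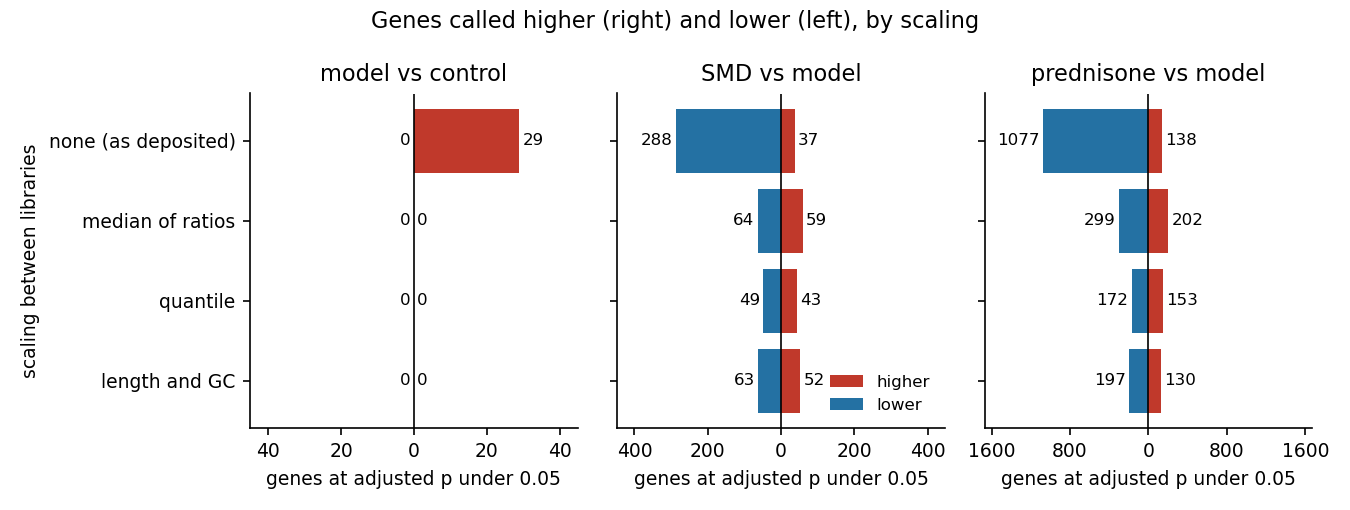
Number of genes called higher (right) and lower (left) at an adjusted p under 0.05 in 3 comparisons, with the deposited values as they are and under 3 corrections. With the deposited values 288 genes fell under SMD and 1077 under prednisone, against 64 and 299 with median-of-ratios scaling.

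SMD was compared directly with prednisone, the reference drug. Zbtb16 was lower under SMD, at 1.20 ± 0.359 against 18.1 ± 4.84 FPKM (log2 fold change -3.10 ± 0.365, SE; n = 5 each, adjusted p = 0.000184), as was Fkbp5 (-2.21). The chaperone genes Hspa1b (-2.46), Hspa1a (-2.23) and Hsph1 (-1.51) were lower under SMD too, as was Ddit4, an inhibitor of mTOR signalling induced by stress (-1.57). Higher under SMD were Plk2 (a polo-like kinase, 0.97), Dbp (0.96), Myct1 (0.93), Ier3 (0.91) and Ackr4, a scavenging chemokine receptor (0.88), and the microRNA gene Mir5620 (0.94).

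Limma called 693 genes, with 327 higher and 366 lower under SMD, and the groups did not overlap for 918 genes (6.08%, where chance gives 0.79%). Of the 19 glucocorticoid-induced genes, 17 were lower under SMD (18 adjusted over the list alone), with a median of -0.89 (camera, adjusted p = 1.35e-20; adjusted p = 0.238 with an estimated correlation). With the fat score as a covariate, 16 of the 19 were lower. Of 20 genes of fatty acid and cholesterol synthesis, 4 were higher under SMD (Msmo1, Hmgcs1, Sqle and Fdft1; 6 adjusted over the list alone), with adjusted p = 0.000189 for the list (adjusted p = 0.509 with an estimated correlation). Among 14 endothelial genes, 3 were higher (Aplnr, Plvap and Kdr) and 1 lower (Vegfc), with 8 and 1 adjusted over the list alone (adjusted p = 0.00142 for the list; adjusted p = 0.966 with an estimated correlation). No interferon response gene passed between the treatments in limma, 2 of 20 were lower at an unadjusted p under 0.05, and the list median was -0.05 (adjusted p = 0.389).

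Each treatment group was also compared with the control group. Under SMD, the largest falls among genes whose libraries did not overlap with those of control included those of Car3, Fabp4 and Zbtb16. Fabp4, the fatty acid binding protein of adipocytes and of alveolar macrophages, fell from 203 ± 189 to 15.4 ± 5.5 FPKM (n = 5 each, adjusted p = 0.038), and Car3 (a carbonic anhydrase), Zbtb16, Cyp2e1 (a cytochrome P450) and Pck1 (an enzyme of gluconeogenesis) fell with log2 fold changes of -3.12, -2.91, -2.62 and -2.37, and Fam107a with -1.47. Bcl3 (an inhibitor of kappa B family member, 0.92), Ifi44l (0.90), Ndnf (0.78), Bcl6b (0.78), Wnt7a (0.74) and Spon2 (0.72) rose. In all, 44 genes rose and 115 fell, and the groups did not overlap for 704 genes (4.66%, where chance gives 0.79%). Fat tissue markers had a median of -1.71, with 1 of 9 falling (Plin4; 7 adjusted over the list alone), and cardiac muscle markers a median of -1.11, with 1 of 9 falling (Myl7; 8 adjusted over the list alone), both at adjusted p = 9.74e-08 (adjusted p = 0.19 and 0.22 with an estimated correlation). Of the interferon response genes, 1 of 20 rose (Usp18, 0.56; 15 adjusted over the list alone), with a median of 0.43 (adjusted p = 8.66e-13; adjusted p = 0.19 with an estimated correlation). Of the glucocorticoid-induced genes, 7 of 19 fell (15 adjusted over the list alone; adjusted p = 1.4e-13; adjusted p = 0.19 with an estimated correlation). That number was 2 with no filter, 4 with arrayWeights or only the groups compared, and 0 with the fat score as a covariate (limma, 7 lower at an unadjusted p under 0.05). It was 2, 4 and 1 without control replicates 1, 3 and 4, 2 without SMD replicate 2, 3 or 4, and 3 without SMD replicate 5. With the fat score as a covariate, limma called 0 genes between SMD and control (933 at an unadjusted p under 0.05), and without control replicate 4, the library with the highest fat score, 19 were called. With median-of-ratios scaling, 73 rose and 126 fell, and with quantile normalization 91 rose and 122 fell.

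Under prednisone, the chaperone genes Hspa1b and Hspa1a rose against control from 4.46 ± 1.58 and 3.37 ± 1.46 FPKM to 19.0 ± 5.57 and 13.6 ± 3.36 FPKM (n = 5 each, adjusted p = 0.00259 and 0.00184). The GTPase genes Tgtp1, Tgtp2 and Iigp1 rose with log2 fold changes of 1.51, 1.5 and 1.49, and Gbp4 rose from 12.9 ± 2 to 42.4 ± 21.3 FPKM. Klhl5 (-1.18), Clec14a (an endothelial lectin, -0.80), Prickle1 (-0.79), Dbp (-0.78), Sox18 (an endothelial transcription factor, -0.75) and Tipin (-0.75) fell. In all, 269 genes rose and 271 fell, and the groups did not overlap for 843 genes (5.58%, where chance gives 0.79%). Of 20 interferon response genes, 8 rose (14 adjusted over the list alone), with a median of 0.48 (adjusted p = 1.17e-12; adjusted p = 0.205 with an estimated correlation). Of 14 endothelial genes, 7 fell (12 adjusted over the list alone), with a median of -0.40 (adjusted p = 9.67e-10; adjusted p = 0.205 with an estimated correlation). Of 12 dendritic cell and MHC class II genes, 5 rose (9 rose and 1 fell adjusted over the list alone), among them Cd209a (0.89) and H2-Ab1 (0.77), and 4 of 17 complement and phagocytic macrophage genes rose (12 adjusted over the list alone), with adjusted p = 2.9e-05 and 8.83e-08 for the lists (adjusted p = 0.477 for both with an estimated correlation). Of the glucocorticoid-induced genes, 1 of 19 rose (Sgk1, 0.40; 7 adjusted over the list alone), with a median of 0.34 (adjusted p = 0.00168; adjusted p = 0.556 with an estimated correlation). In limma, 0 of the 19 were called with no filter, eBayes without trend, the fat score as a covariate or only the groups compared (7, 7, 7 and 8 higher at an unadjusted p under 0.05), and 3 with quantile normalization, arrayWeights or the length and GC correction. Sgk1 lost its call without any 1 library other than control replicate 4, model replicate 1, 3 or 4, or prednisone replicate 4. Fat tissue and cardiac muscle markers had medians of -1.35 and -0.65, with 0 of 9 of either list passing in limma and 6 and 4 lower at an unadjusted p under 0.05 (camera adjusted p = 0.000388 and 0.00125; adjusted p = 0.477 and 0.531 with an estimated correlation). With the fat score as a covariate, 78 genes were called between prednisone and control, and Gbp4, Klhl5, Dbp and Sox18 were not. In that fit, 2 of 20 interferon response genes rose, and limma called 0 of the endothelial, the dendritic cell and MHC class II, and the complement and phagocytic macrophage genes, with 10 lower, 7 higher and 7 higher at an unadjusted p under 0.05.

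The study's design also asks whether the treatments moved genes of the model back. Of the 29 genes that rose in the model, 11 fell under SMD, among them Ighg2b, Igha, Ccl17 and Alkal1. Under prednisone, 12 of the 29 fell, among them Igha, Gpx1 (a glutathione peroxidase) and Sec61b (a subunit of the protein translocation channel). Both treatments moved back 6 of them, among them Igha, Trmt112, Pkig, Atpif1 and Hacd3. Under SMD, 2 of the 29 still differed from control, and under prednisone 12 did. These 2 counts rest on unlike p limits, since 159 genes in all were called between SMD and control and 540 between prednisone and control. They do not rank the treatments, and a gene that did not pass is not thereby back at the control level. All 29 had a log2 fold change under SMD opposite in sign to that of the model, and 25 did under prednisone, but the shared model libraries alone give such signs: in simulations of unchanged groups, the 29 rises with the smallest p had 25.5 and 26.3 opposite signs on average. H2-Ab1, H2-Eb1 and Cd74 were not among the genes moved back by either treatment.

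Because both comparisons hold the same model libraries, genes can appear to move back by chance. Simulations of unchanged groups called a gene between model and control in 4 of 100, so their counts of genes moved back (at most 0 for SMD and 1 for prednisone) say nothing of the shared libraries. Where lists as long as the real ones were instead taken from each simulation by the smallest p, the median number moved back was 8.5 for SMD and 15.5 for prednisone, and 40 and 66 of the 100 simulations gave as many as the real 11 and 12. Independent lists of calls would share 0.55 and 2.07 genes. Across all genes, which are not independent replicates, the effect of the model had a correlation of -0.49 with that of SMD and -0.39 with that of prednisone, against -0.46 and -0.48 in the simulations. The covariances were -0.0258 and -0.0192, against -0.0121 ± 0.0082 and -0.0124 ± 0.0068 simulated. Where the model libraries were split so that each comparison had its own, the median over 20 splits was 0 for both treatments, with ranges of 0 to 1 and 0 to 15. Each comparison then held only part of the model libraries, so fewer genes can pass. These low counts therefore do not decide whether the shared libraries gave the overlap. Under median-of-ratios scaling or quantile normalization the counts were 0 for both treatments.

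The effects of SMD and prednisone were compared with each other in the same way. Of the genes called against the model, 75 fell under both treatments, 0 rose under both and 7 were called in opposite directions, where independent lists would share 20.5, 0.3 and 5.3. Calls for both treatments arose in 1 of the 100 simulations, so the shared falls were again compared with lists as long as the real ones: these shared a median of 118 falls, and 71 of the 100 simulations gave 75 or more. With split model libraries the median of falls called under both was 2.5, but each comparison then held fewer model libraries. That count therefore cannot be set directly beside the 75. Across genes, which are not independent replicates, the log2 fold changes of the treatments had a correlation of 0.46, against 0.49 ± 0.2 in the simulations. Their covariance was 0.0234, against 0.0134 ± 0.0076 simulated, a difference of 0.01, and the highest simulated covariance was 0.0337. With split model libraries the median covariance was 0.0108.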

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

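The tests of collection time, scaling and fat score described here, the counts over other splits of the libraries and the simulated lists of equal length were chosen after the results were seen. Of 435 sets of 5 libraries, 27 held a library far from the others of its group by Dixon's test, where 21.8 are expected by chance. Each is given as a value in FPKM, with the range of the other 4 libraries of its group.

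In the control group, replicate 1 had the highest sum of FPKM values, 522361 against 406764 to 415121, and also stood apart for Ighg2b (0.687 against 0.151 to 0.285) and Nfil3 (1.75 against 1.05 to 1.21). Control replicate 4 stood apart for Dnajb1 (17.1 against 8.96 to 10.6), Fam107a (12.3 against 3.54 to 5.91), Klhl5 (64.2 against 48.1 to 51.5) and Scgb1a1 (46654 against 52461 to 54273). Zbp1 was at 3.55 in control replicate 2 against 2.22 to 2.49, and Tbxas1 at 2.22 in control replicate 3 against 0.192 to 0.262.

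In the model group, replicate 1 stood apart for the immunoglobulin genes Ighg2b (14.4 against 1.84 to 5.01) and Iglc2 (76.4 against 19.3 to 32.9). Replicate 4 stood apart for Fdps (22.4 against 31.3 to 34.6), Ndufb8 (68.1 against 80.3 to 84.4) and Smg1 (9.89 against 5.17 to 6.27). Replicate 5 stood apart for Klf15 (38.3 against 22.8 to 26.3), Mcm2 (2.86 against 1.40 to 1.68), Tppp3 (289 against 182 to 207) and Zfp973 (2.21 against 0.841 to 1.16).

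In the SMD group, replicate 1 stood apart for 4 genes, Glul (162 against 101 to 117) and Per1 (23.5 against 14.7 to 16.5) from the list of glucocorticoid-induced genes, and Klf15 (19.9 against 7.40 to 10.8) and Fam107a (2.51 against 1.10 to 1.44) from the ranking. The others were Il33 in SMD replicate 2 (13.9 against 17.7 to 19.2), Ddah2 in replicate 3 (30.8 against 36.2 to 38.3), Retnla in replicate 3 (48.9 against 36.2 to 39.5) and Aplnr in replicate 4 (24.3 against 15.4 to 17.5). In the prednisone group, Mir1966 was at 2.25 in replicate 1 against 3.34 to 3.64.

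Of the 19 glucocorticoid-induced genes, 8 were called lower in SMD than in model libraries and 17 lower than in prednisone libraries (camera adjusted p = 0.483 and 0.238 with an estimated correlation). Scaling between libraries is argued against as the whole cause of the lower list median against the model, which went from -0.746 to -0.675 under median-of-ratios scaling (quartiles -0.829 and -0.481; all genes, 0.00233), but the calls depended on it, going from 8 to 3, and to 2 with quantile normalization. Against prednisone, less fat tissue in the SMD libraries is argued against too, since with the fat score as a covariate the median was -0.898 and 16 of the 19 genes were called lower, against 17 without it. Against the model, fat tissue stays open: with the covariate the median went from -0.746 to -0.614, its median SE from 0.2 to 0.23, and the calls from 8 to 0 (16 of 19 lower at an unadjusted p under 0.05 in limma, against 17), with 2 left at the p limit of 0.00107 that held without the covariate and 2 of the first 8 under its stricter limit of 4.45e-05, so that larger p-values and a stricter limit both took calls. Another time of collection also stays open, since times are not given and a log2 change of Dbp of -0.153 cannot exclude it. On log2(FPKM + 0.1), Ciart (-0.765), Nfil3 (-0.551) and Per2 (-0.522) were lower in SMD than in model libraries. Their adjusted p-values in exact permutation tests, adjusted only over the few clock genes tested, were 0.0318, 0.0318 and 0.0424. These genes were chosen after their values were seen, and Ciart and Per2 were already called in limma. The permutation tests thus add no separate support, and Nfil3 was not called in limma (adjusted p = 0.0594). Dbp, Nr1d1 (0.0211), Arntl, Npas2 and Clock did not pass in the permutation tests. An effect of SMD itself remains a hypothesis.

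For each comparison, other splits of the same 10 libraries into groups of 5 were fitted, 100 with the real split included. The real split gave the highest count in all 6 comparisons, so that 1 of 100 splits gave as many genes, the smallest share that 100 splits allow. The splits were fitted only on the values without further scaling. With median-of-ratios scaling or quantile normalization the real split called 0 genes in limma between model and control (1919 and 1909 at an unadjusted p under 0.05), so for that comparison the splits do not exclude chance under those scalings. The real counts and the highest of the other splits were 29 and 20 for model against control, 325 and 5 for SMD against model, 1215 and 256 for prednisone against model, 693 and 27 for SMD against prednisone, 159 and 3 for SMD against control, and 540 and 4 for prednisone against control. For model genes moved back, the splits shuffled the libraries of control, model and the treatment together, so treatment libraries could enter the model group. Here 1 of 100 splits gave as many for SMD (11, highest other 3) and 2 of 100 for prednisone (12, highest other 276). The split with 276 gave many times the real count. Which libraries it rests on was not examined, so whether it reflects a structure of these samples is unknown. The other splits moved back a median of 0 genes and so do not exclude the shared model libraries as the source of these overlaps: in simulated lists as long as the real ones, 40 and 66 of 100 gave as many.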

How the results depend on the processing

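The fat score covariate and the correction for gene length and GC content were chosen after the data were seen. No named gene that was called turned its direction under an alternative that tested it, and the stricter filter left 52 of 274 values of named genes untested. Most of these genes were chosen for large called changes, so a turn in direction was unlikely from the start. Calls were lost for 144 of the 274 values with the fat score, 115 with no filter, 96 with only the groups compared and 69 with quantile normalization, against 6 with a pseudocount of 0.1. The 274 include genes given whatever their result, and those not called cannot lose a call. The shares of called values that were lost are therefore larger. The cause of the differences in count was not tested, except that dropping the filter tests more genes. Leaving out libraries or groups, or splitting the model libraries, also leaves fewer samples. Depth is unknown, so its effect on these counts could not be examined.

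For model against control (29 genes), limma called 0 genes with median-of-ratios scaling, quantile normalization, eBayes without trend, only the groups compared, the fat score covariate, and the length and GC correction, with 1919, 1909, 2342, 2234, 2186 and 1935 genes at an unadjusted p under 0.05. It called 2 with no filter, 53 with the stricter filter, 103 with arrayWeights and 4 at an absolute log2 fold change of at least 1. Counts without 1 library ranged from 0 to 111.

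For SMD against model (325), the counts were 123 with median-of-ratios scaling (99 shared), 92 with quantile normalization, 122 with no filter, 53 with only the groups compared, 21 at a log2 fold change of 1, 14 with the fat score and 115 with the length and GC correction, and 75 to 527 without 1 library. For prednisone against model (1215), they were 501 (428 shared), 325, 748, 710, 26, 647 and 327 under the same settings, and 608 to 1695 without 1 library.

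For SMD against prednisone (693), 453 were called with no filter and 28 at a log2 fold change of 1. Without 1 library the counts ranged from 457 (SMD replicate 4) to 723. For SMD against control (159), 35 were called with no filter, 92 with arrayWeights, 20 at a log2 fold change of 1 and 0 with the fat score (933 at an unadjusted p under 0.05). Without 1 library they ranged from 19 to 217: 66, 97, 19 and 81 without control replicates 1, 3, 4 and 5, and 45, 38, 47 and 37 without SMD replicates 2 to 5. For prednisone against control (540), 259 were called with no filter, 256 with only the groups compared, 26 at a log2 fold change of 1 and 78 with the fat score. Without 1 library they ranged from 229 to 662: 303 and 335 without control replicates 1 and 4, and 229 and 265 without prednisone replicates 2 and 3.

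The number of model genes moved back by SMD (11) was 0 with median-of-ratios scaling, quantile normalization, eBayes without trend and split model libraries, 1 with no filter, 3 with only the groups compared, 4 at a log2 fold change of 1 and 40 with arrayWeights. For prednisone (12) it was 0 under the same 4 settings and with only the groups compared, 1 with no filter and at a log2 fold change of 1, 22 with the stricter filter and 50 with arrayWeights. Both numbers were 0 without any 1 of the control replicates, model replicate 1 or 2, SMD replicate 1, 2 or 4, or prednisone replicate 3 or 4. They were 6 and 7 without SMD replicate 5 and 47 and 62 without model replicate 4, and prednisone moved back 19 without prednisone replicate 2, so the ranges were 0 to 47 and 0 to 62. The covariance of the treatments' effects (0.0234) was 0.0429 with a pseudocount of 0.1 and 0.0108 with split model libraries, and 0.0219 to 0.0296 without 1 library.

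Replicate numbers are shared between groups. Over 30 pairs with the same number, the correlation of deviations from the group means ranged from -0.18 to 0.237, 6 were over 0.1, and 2 of 20 libraries correlated best with their own number. No sign was thus found that the numbers pair the libraries, but a pairing is not excluded. With the replicate block, limma called 0 genes for model against control (2380 at an unadjusted p under 0.05), 323 for SMD and 1074 for prednisone against the model, 650 between the treatments, 171 for SMD and 423 for prednisone against control, and 0 genes were moved back by either treatment. For SMD against the model, 13 of the 19 glucocorticoid-induced genes were then called lower.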

Other observations

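The tests of scaling described here, the exact tests of single clock genes other than Arntl and Npas2, and the choice of genes listed at 0 were made after the results were seen. Several groups of genes were not described above. In the model, alternatively activated macrophage genes had a median log2 fold change of 0.31 against control, with 1 of 8 rising (Ccl17; 3 adjusted over the list alone; camera adjusted p = 0.0113; adjusted p = 0.365 with an estimated correlation). Extracellular matrix genes had a median of 0.34 and ciliated cell genes a median of 0.24, with 0 of 18 passing in either list over all genes and 3 and 7 adjusted over the list alone (adjusted p = 0.000954 and 0.0012; adjusted p = 0.568 and 0.573 with an estimated correlation). Club cell genes had a median of -0.18 in the same comparison (adjusted p = 0.000108; adjusted p = 0.365 with an estimated correlation).

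Under prednisone, smooth muscle contractile genes had a median of -0.32 against the model, and 2 of 13 fell, the actin Acta2 (-0.49) and the intermediate filament gene Des (-0.36), with 6 adjusted over the list alone (adjusted p = 0.061 for the list), while 1 fell with the fat score and, in limma, 0 with median-of-ratios scaling or quantile normalization (3 at an unadjusted p under 0.05 in each). Against control, 5 of 13 fell (7 adjusted over the list alone; 1 with the fat score; adjusted p = 4.57e-06; adjusted p = 0.205 with an estimated correlation). Proliferation genes had a median of 0.34 against the model, and 1 of 16 rose, Mki67 (0.54), which marks cycling cells (4 adjusted over the list alone; in limma, 0 with quantile normalization or the fat score, and 5 and 6 at an unadjusted p under 0.05; adjusted p = 1.74e-07; adjusted p = 0.845 with an estimated correlation). Tbxas1, thromboxane synthase, rose under prednisone against control with a log2 fold change of 1.63. In control it was at 2.22 FPKM in replicate 3 and at 0.192 to 0.262 FPKM in the other libraries, so its control level is uncertain.

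More genes fell than rose under prednisone against the model, 88.6% of the calls. Gene length and GC content stay open: with the trend of each library removed, 88.1% of calls fell where the library mean was kept and 60.2% where it was not, and since keeping or removing the mean itself sets the share (median change of all genes -0.054 and -0.00019), the bound written before the first of these values was seen decides nothing. Scaling between libraries stays open too, since 59.7% fell under median-of-ratios scaling, but such centring likewise sets the share, and the true total of RNA is unknown. A first test compared groups of genes by length (the longest group minus the shortest, 0.175 in median log2 change) and was read as excluding scaling, and it was replaced after its result was seen, because a trend with length can stand beside a shift in scale. A real effect of prednisone may add to the excess but cannot be separated from scaling or from gene length and GC content here.

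Dbp and Nr1d1 were lower and Nfil3 higher in prednisone than in model libraries. Each had p = 0.00794 in exact two-sided permutation tests over 252 arrangements (adjusted p = 0.0212), the smallest p that these arrangements allow. Dbp and Nr1d1 were named because their libraries did not overlap, which fixes this p, so for these genes the tests add nothing to the ranking. A shift in scale is argued against, since Dbp had a log2 change of -1.05 under median-of-ratios scaling. A different phase of the daily clock, from the drug or from another time of collection, is a candidate explanation and would raise Arntl and Npas2. Arntl differed by 0.157 (exact p = 0.151) and Npas2 by 0.153 (exact p = 0.381) on log2(FPKM + 0.1), so the tests leave this open. Arntl lies near the floor, at 0.301 ± 0.0313 FPKM against 0.261 ± 0.0481 FPKM, and collection times are not given.

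Among 8444 genes with a median of at least 5 FPKM, 3 were listed at exactly 0 in some libraries. An exact 0 in values without counts can be a failed estimate. Junb, an immediate early transcription factor and a member of the immediate early and heat shock list, was listed at 0 in control replicates 1 and 5 and SMD replicate 4, and at 22.7 to 55.9 FPKM in the others. Hist2h2aa1 was at 0 in SMD replicates 1 and 4 and prednisone replicate 3, and at 5.85 to 13.7 FPKM in the others, and Gm26619 was at 0 in prednisone replicate 3 and at 121 to 162 FPKM in the others.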
